A study of Mus musculus with 66 samples.

How the data were processed

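RNA from mouse liver and from laser-captured trophoblast giant cells was measured with a NanoString nCounter probe panel, which counts colour-coded reporter probes hybridised to single transcripts without amplification. Per the labels' protocols, liver RNA was extracted with trizol and giant cell RNA with the PicoPure kit. The mice were of the FVB background, per the labels, which do not give their sex. No comparison could therefore be balanced for sex. The series notes state that deletion was checked by PCR genotyping of DNA from each sample. The panel held 200 target probes, 10 reference probes, 6 spike-in controls and 8 negative controls, and 66 samples (48 liver, 18 giant cell) filled 1 lane each.

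The deposited raw table holds whole-number counts per probe and lane, with control and reference probes included and no scaling stated by the authors. The deposited processed table holds a scaled signal per target probe, and the authors' method for it is not stated. Set against the raw counts of the same lanes, the processed signal of 52 numbered columns followed from the raw counts (Pearson's r across probes from 0.979 to 1). The other 10 columns, the wild-type giant cells from E8.5 to E17.5, did not (r from 0.481 to 0.844), so the raw counts were used throughout and the processed signal served as an alternative. Probes within a lane are not independent replicates, and these values of r describe the tables only.

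The labels of 179 target probes were the same in both tables. The remaining 21 probes carried labels that differed between the tables and were left out. Of 210 labelled probes, 206 accessions were matched to the RefSeq annotation of assembly GRCm38.p6, used for gene names only. By accession, 22 probes took another symbol than their label, such as Fzr1 for a probe labelled Cdh1 and Angptl8 for one labelled Gm6484. The files name no genome build, so no coordinates are given. The control rows of 22 lanes stood out of order and were put back by their values. Among the raw columns, 4 lanes of 3-week wild-type liver shared their headings, as the numbers 1 and 2 each stand on 2 columns. They entered the wild-type group without a number and are called unnumbered.

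The background of each lane was the mean of its negative controls plus 2 SD. A probe was tested where every sample of at least 1 group lay above it, which left 161 probes in liver, 53 in giant cells and 164 in a joint fit of both tissues. The scale of each lane was the geometric mean of the listed reference probes Actb, B2m, Gapdh, Oaz1 and Pgk1. Rpl27 was listed too but was above background in 6 of the 48 liver lanes and 0 of the 18 giant cell lanes. It was left out by a rule of at least 50 percent of lanes, set after the counts were seen. In giant cells B2m, Gapdh and Oaz1 were each above background in only 9 of 18 lanes. These lanes were not spread evenly over the groups compared, as given with the results. Normalised counts are raw counts divided by this scale, with no background taken off, and are given as mean ± SD. By a rule added after the results were seen, a log2 fold against a group with under 50 percent of its samples above background is given as a bound (at least, or lower): the other group's mean against that group's mean of, per sample, the higher of count and background. No fold is given where both groups are so low, nor a difference between effects where any of its 4 groups is. Each tissue was scaled on its own, so normalised counts compare within a tissue only.

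Differences were tested with edgeR 4.0.16 (quasi-likelihood F-test, 1 coefficient per group, 2-sided), liver and giant cells apart, and adjusted by Benjamini-Hochberg over the probes tested at a threshold of 0.05. Log2 fold changes are given with their standard error. All adjusted p-values for genes come from this test unless another tool is named, and those for gene lists come from the fry test of limma 3.58.1, adjusted over the lists tested in a comparison. Lists with at least 3 tested probes were the E2F and pocket protein family, G1/S and DNA replication, G2/M and mitosis, trophoblast giant cell genes and other trophoblast genes. The study chose the panel, so no list was compared with the other probes. Lists, comparisons, tests, the probe filter and the rule for the genes named were fixed before the data were examined. The rule named up to 12 rises and 8 falls in the comparisons of double mutants with wild type and of ages, up to 5 each way in the others, and up to 3 members per list with the smallest p. A rise or fall had to be past the threshold with every later or mutant sample on its side of the other group's mean. For tests over all ages it named the 10 genes with the smallest p. Reference probes were not named by it.

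Alternatives were another scale (TMM, spike-ins, all 10 reference probes, all 6 listed probes, each probe left out), DESeq2 1.42.0, limma on the log2 processed signal with 1 or 10 added, no filter, a stricter filter, no dispersion trend, background subtraction, the E2F list without E2f7 and E2f8, the replicate number as a block, and each lane left out. The 66 lanes fell into 3 sets by the ratio of the 2 highest spike-ins (0.128 to 0.209 in 1 set of 20 lanes, 0.288 or more in the others), and by the displaced control rows. These lane sets were used as a block and for values within a set. Each mutant liver group held 3 lanes of set 1 and 1 lane of set 2. Mutant and wild-type giant cells up to E10.5 were in set 2 and later stages in set 3. Liver at 2 months was in sets 1 and 2 and at E13.5 in set 3, and wild-type liver at 3 weeks was in all 3.

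Where at least 3 pairs of samples shared a replicate number, the pairs did not all deviate together from their group means. The double and E2f7 mutant livers at 3 weeks were the exception, since all 4 pairs correlated by more than 0.1 across probes (0.116 to 0.303). The labels do not say what the number marks, so the pairing comes from this check. In both of these mutant groups replicate 4 was the lane of set 2. Replicate 3 was a shallow lane in both (12215 counts in double and 28408 in E2f7 mutants). For these pairs lane set or depth cannot be told apart from a pairing of the mice.

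The tests, but not the scaling, the probe filter or the lane sets, were tried on simulated data. In 20 draws 40 of 161 probes were changed (12 of 53 in giant cells). A further list of probes was raised by less than 2-fold, and calls of these were not counted as false. The real scale of each lane was used both to draw and to fit the counts. In the simulated E2f8 mutant livers at 3 weeks, edgeR recovered 81.5% of 2-fold and 98.8% of 4-fold changes, and 2.95% of its calls were false. For the double mutant livers at 2 months it recovered 71.5% and 96.8%, and for 2 months against E13.5 it recovered 72.3% and 95.8%. For the double mutant giant cells it recovered 0.833% of 2-fold and 6.67% of 4-fold changes, and 10.0% of its calls were false. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.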

Results

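Messenger RNA was counted with a probe panel in liver and in trophoblast giant cells of mice lacking E2f7, E2f8 or both, and in wild-type mice over age. E2f7 and E2f8 encode the atypical E2F proteins, which repress cell cycle genes. Hepatocytes and trophoblast giant cells are both cell types that become polyploid. In liver the genes were deleted with Albumin-Cre, which acts in hepatocytes, and in giant cells the deletion was in the germline. At 3 weeks there were 6 wild-type livers and 4 of each mutant genotype, and at 2 months there were 4 of each genotype. Wild-type liver was also taken at E13.5 (n = 3), at birth, 1, 2 and 6 weeks (n = 2 each) and 1 day after weaning at 3 weeks (n = 3). Giant cells were captured from wild-type mice at E6.5, E8.5, E10.5, E13.5, E15.5 and E17.5 and from the 3 mutant genotypes at E10.5, with n = 2 each.

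The total count of the target probes per sample was 12215 to 177320 in liver (median 63931) and 1955 to 50600 in giant cells (median 11050.0). A liver sample had 118 to 179 of all 200 target probes above its background, and a giant cell sample had 19 to 93. The most abundant probe took a median of 54.1% of the giant cell counts but 3.84% at E6.5, against 17.9% in liver. Background counts were 2.16 to 77.2 in liver and 12.5 to 27.6 in giant cells.

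The targeted genes come first. E2f8 was above background in all 6 wild-type livers at 3 weeks (43 to 107 raw counts) and in all 4 E2f7 mutants (40 to 140). In E2f8 mutants it was above background in 0 of 4 samples (3 to 17) and in double mutants in 1 of 4 (3 to 20). At 2 months E2f8 reached background in only 1 of 4 wild-type livers (19 to 51), with 2 to 20 in E2f8 mutants and 1 to 18 in double mutants. E2f7 lay near background at 3 weeks, above it in 3 of 6 wild-type livers (10 to 23) and in 1 of 4 E2f7 mutants (5 to 25). Its counts therefore do not check the E2f7 genotype. In giant cells E2f7 was above background in no sample and E2f8 in only 1 sample each at E8.5 and E10.5, and neither was tested there. The files do not say which part of either transcript the probes bind.

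Loss of E2f7 alone in liver was compared with wild type to ask which genes depend on it. No probe of 161 passed edgeR's threshold at 3 weeks or at 2 months. At an unadjusted p under 0.05 there were 9 probes at 3 weeks (4 higher, 5 lower) and 19 at 2 months (2 higher, 17 lower). DESeq2 called 2 and 1 probes, and limma on the processed signal 0 and 1. With lane set as a block edgeR called 3 and 3 (1 higher and 2 lower at each age), and with lane set 1 alone 7 and 1. E2f8 differed by 0.30 ± 0.29 log2 at 3 weeks (adjusted p 0.74, higher in 4 of 4 mutants). E2f8 and E2f7 at 2 months lay near background, and no fold of them is given. For E2f7 at 3 weeks, above background in 1 of 4 mutants, the bound is 0.33 log2 or lower, which leaves its direction open. At 3 weeks none of the 9 E2F family, 16 G1/S and 9 G2/M members was called (fry adjusted p 0.918, 0.918 and 0.807). At 2 months no member was called either, while fry called the E2F family as lower on balance (median -0.268, adjusted p 0.0455). Its members with the smallest p were E2f8, E2f6 (-0.30 ± 0.16) and E2f7, and without E2f7 and E2f8 the other 7 did not pass (adjusted p 0.0807). The G1/S and G2/M lists had adjusted p 0.25 and 0.25. The E2F call ended under TMM scaling (adjusted p 0.799; 0.0237 to 0.952 over all alternatives), whose median over all probes lay 0.20 log2 higher. It also ended without wild-type replicate 1, 2 or 4 or mutant replicate 3 or 4 (adjusted p up to 0.223). At 3 weeks leaving out wild-type replicate 4 gave 4 calls, mutant replicate 4 gave 2 and 1 unnumbered wild-type sample gave 1, and at 2 months leaving out wild-type replicate 1 gave 1.

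Loss of E2f8 alone at 3 weeks gave more calls than any other mutant liver against wild type. Rgs16, a regulator of G protein signalling, fell from 931 ± 987 normalised counts (SD, n = 6) to 61.5 ± 22.6 (n = 4), a log2 change of -3.91 ± 0.76 (SE). Igfbp1, an insulin-like growth factor binding protein, fell by 2.99 ± 0.69 log2. Without wild-type replicate 4, whose Igfbp1 was 14560.3 where the next highest was 2839.5, that change was -1.49 and still past the threshold. E2f8 itself fell too (-2.41 log2 or lower, as no mutant lay above background). Angptl8, a secreted regulator of plasma triglycerides, rose from 120.5 ± 31.6 to 532 ± 104 (2.13 ± 0.37 log2, adjusted p 8.13e-05). Each of these genes lay on the same side of the wild-type mean in 4 of 4 mutants. Rgs16 and Igfbp1 were also lower in wild-type livers after weaning, set against the same 6 wild types. Both comparisons rest on these wild types, whose values spread widely, so the 2 results are not independent. Whether the falls are particular to loss of E2f8 is thus not settled.

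In all, edgeR called 11 genes higher and 13 lower of 161, with 50 at an unadjusted p under 0.05. Among the rises were the transcription factor Cux2 (1.80 ± 0.39), the manganese transporter Slc30a10 (1.27 ± 0.22), Tspyl4 (at least 0.82) and the prostaglandin D synthase Ptgds (at least 0.65), the last 2 above background in 2 of 6 wild types each. Among the falls were the ganglioside synthase B4galnt1 (-2.49 ± 0.78) and the p38 kinase activator Map2k6 (-1.24 ± 0.26). The remaining 14 calls are named in the plot of fold changes at 3 weeks. Their adjusted p lay between 0.000929 for Pcsk6 and 0.0416 for the linker histone gene H1f2. Of the E2F family 1 of 9 members was called, E2f8, while E2f1 (-0.58 ± 0.24) and Rb1 (0.18 ± 0.17) were not. The family did not pass fry in 1 direction (adjusted p 0.084). It passed in either direction (0.0114) only with the deleted gene in the list, since without E2f7 and E2f8 it did not (adjusted p 1). None of the 16 G1/S members was called (adjusted p 0.143), as with Ccnd1 at -0.65 ± 0.28 and Ccne1 at -0.53 ± 0.24. Of the G2/M list 1 of 9 was called, the tubulin gene Tubb4b (0.87 ± 0.29, list adjusted p 0.884).

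The balance of rises and falls followed the scale: 16 and 12 under TMM, 16 and 10 with all 10 reference probes, 26 and 6 with the spike-ins, and 7 and 24 on the processed signal. The median probe was -0.11 log2, against 0.00 under TMM and 0.16 with the spike-ins, and the directions of Rgs16, E2f8, Angptl8 and Slc30a10 held in all of these. B4galnt1 lost its call without mutant replicate 2, 3 or 4 (adjusted p up to 0.0842), Ptgds without mutant replicate 3 (0.16), and Tubb4b without mutant replicate 4 or either of 2 wild-type samples (0.542). Without mutant replicate 1 the count was 16 and B4galnt1 was at -5.36. In the other direction, Ccnd1 was called without mutant replicate 3 (adjusted p 0.00441), E2f1 without that sample or wild-type replicate 3 (0.0243 and 0.0214) Ccne1 without 1 unnumbered wild-type sample (0.0436) and the G2/M member Wee1 as lower (-0.73) without mutant replicate 4 (0.00845). Without wild-type replicate 3 the E2F family and the G1/S list passed fry as lower (adjusted p 0.00941, E2f8 included, and 0.034).

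**Figure D1:**
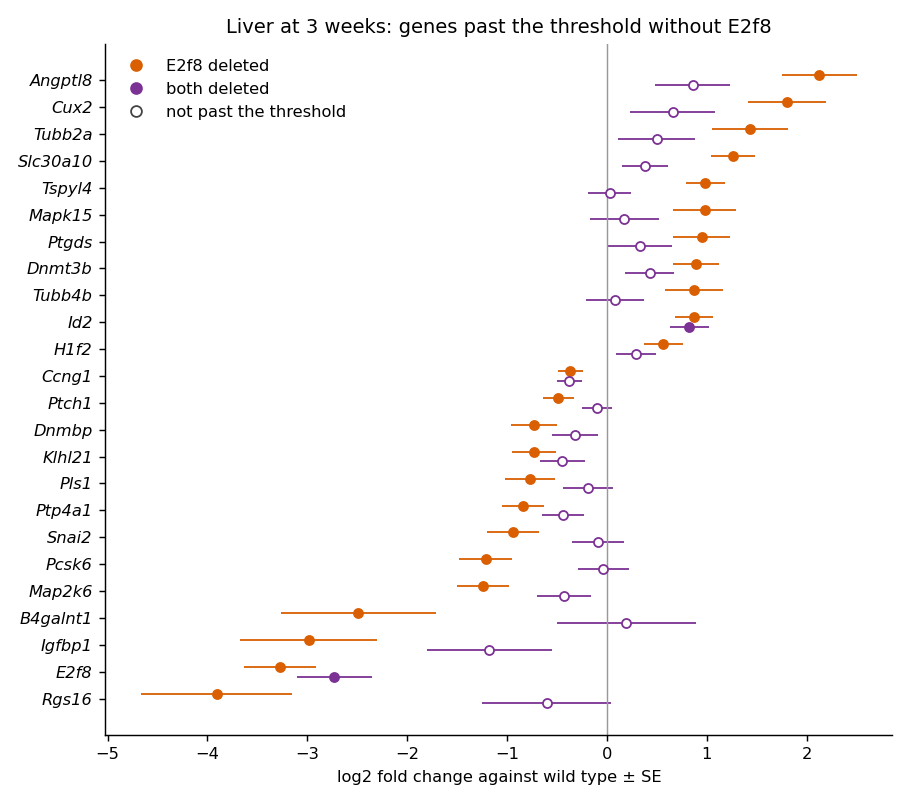
Log2 fold change against wild type with standard error (horizontal axis) for the 24 genes called by edgeR in E2f8 mutant liver at 3 weeks (orange, n = 4), beside the double mutants (purple, n = 4); open symbols did not pass the threshold, and both use the same 6 wild-type samples. Rgs16 (-3.91) and Angptl8 (2.13) lie at the ends for the E2f8 mutants, and E2f8 and Id2 were also called in the double mutants. The point of E2f8 rests on counts at background in the mutants.

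Liver lacking both genes was compared with wild type to ask what loss of both does. At 3 weeks E2f8 fell (-2.19 log2 or lower), with 1 of 4 double mutants above background. Akr1b3, which encodes aldose reductase, fell from 366 ± 219 normalised counts (n = 6) to 129 ± 16.9 (n = 4; -1.48 ± 0.36 log2, adjusted p 0.0103). The glutathione S-transferase gene Gstk1 fell from 2931 ± 1037 to 1564 ± 324 (-0.91 ± 0.23, adjusted p 0.0128), and the interferon-inducible Ifi203 changed by -1.05 ± 0.29. Id2, an inhibitor of DNA binding by helix-loop-helix proteins, rose from 1333 ± 170.2 to 2362 ± 500.2 (0.83 ± 0.19), as it did after weaning against the same wild types. Each moved the same way in 4 of 4 mutants. Within lane sets 1 and 2 the log2 ratios were -0.94 and -1.93 for Akr1b3 and -0.85 and -0.96 for Gstk1. Lane set 2 held only 1 double mutant and 1 wild type.

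These 5 genes (1 higher, 4 lower) were all that edgeR called of 161, with 17 at an unadjusted p under 0.05. Of the E2F family only E2f8 was called, and E2f3 (0.47 ± 0.22) and E2f5 (-0.15 ± 0.18) were not (fry adjusted p 0.218). No G1/S member was called (0.913), as with Rrm2 at 0.83 ± 0.29 and Ccne2 at -0.46 ± 0.23, and no G2/M member (0.913), as with Pttg1 at -0.22 ± 0.22, while Cdk1 was above background in no sample of either group. Rises and falls were 3 and 4 under TMM, 9 and 2 with the spike-ins, 2 and 4 with all 10 reference probes and 0 and 6 on the processed signal, with the median probe at -0.02 and, with the spike-ins, 0.23. Without double mutant replicate 2 only E2f8 remained past the threshold, without replicate 3 the count was 2, and without 1 unnumbered wild-type sample it was 3. Akr1b3 lost its call without replicate 2 or 3 (adjusted p up to 0.0665), Gstk1 without replicate 1, 2 or 3 or that wild-type sample (0.0824), Id2 without replicate 2 (0.0824), and Ifi203 without any double mutant or either of 2 unnumbered wild-type samples (0.137). The folds moved little in these fits: -1.49 and -1.41 for Akr1b3, -0.90 to -0.79 for Gstk1, 0.71 for Id2 and -1.07 to -0.87 for Ifi203. Rrm2 was called without double mutant replicate 1 (0.0452), and the E2F family, E2f8 included, passed fry without wild-type replicate 3 (0.0444).

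At 2 months E2f8 was called lower in the double mutants, but no fold is given, as 1 of 4 wild types and 0 of 4 double mutants lay above background. The hydroxysteroid dehydrogenase gene Hsd17b6 fell from 2611 ± 1042 (n = 4) to 1093 ± 536 (n = 4; -1.26 ± 0.31 log2, adjusted p 0.02). Id3 fell from 688 ± 165 to 306 ± 111 (-1.16 ± 0.31, adjusted p 0.0341), each in 4 of 4 mutants. No gene was called higher by edgeR, and 14 probes had an unadjusted p under 0.05 (2 higher, 12 lower). The lists gave fry adjusted p 0.353 (E2F family, 1 of 9 called), 0.456 (G1/S, 0 of 16) and 0.609 (G2/M, 0 of 9), with Ccnd1 at -0.87 ± 0.31. DESeq2 called 3 genes, and the count was 0 with only the 2 groups fitted. Without wild-type replicate 4 or double mutant replicate 4 the count was 0, and without wild-type replicate 1 or double mutant replicate 2 it was 1. Hsd17b6 lost its call without any of these 4 samples (adjusted p up to 0.206), Id3 without them or double mutant replicate 3 (0.248), and E2f8 without replicate 4 of either group (0.0662). Ccnd1 was called without wild-type replicate 3 (0.0424).

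Prlr, the prolactin receptor gene, was higher in livers lacking E2f8 alone at 2 months than in wild type. It was 395 ± 127.9 against 185 ± 94.6 (n = 4 each, 1.09 ± 0.25 log2, adjusted p 0.00773). The ephrin gene Efna1 fell from 579 ± 150.1 to 248 ± 45.1 (-1.23 ± 0.33, adjusted p 0.029), and Ccne1, the cyclin E1 gene, was lower (-0.0895 or lower, with 2 of 4 wild types and 1 of 4 mutants above background). E2f8 was called lower too, with no fold given (1 and 0 of 4 above background). These were the 4 calls of edgeR, each in 4 of 4 mutants, with 17 at an unadjusted p under 0.05. Of the E2F family 1 of 9 was called (fry adjusted p 0.392), of the G1/S list 1 of 16 (0.612) and of the G2/M list 0 of 9 (0.613). Adjusted over the list alone, 2 G1/S members passed, Ccne1 and Ccne2. Rises and falls were 2 and 2 with the spike-ins and 2 and 1 with all 10 reference probes. Leaving out wild-type replicate 3 or 4 or mutant replicate 3 left 1 call, and leaving out wild-type replicate 2 or mutant replicate 1 left 2. Prlr lost its call without wild-type replicate 2 or 3 or mutant replicate 3 (adjusted p up to 0.0832), Efna1 without wild-type replicate 1, 3 or 4 or mutant replicate 1 or 3 (0.1), E2f8 without wild-type replicate 4 (0.0609) and Ccne1 without any sample but wild-type replicate 1 (0.221). Ccne2 was called without wild-type replicate 1 (0.0386) or mutant replicate 2 (0.0418).

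**Figure D2:**
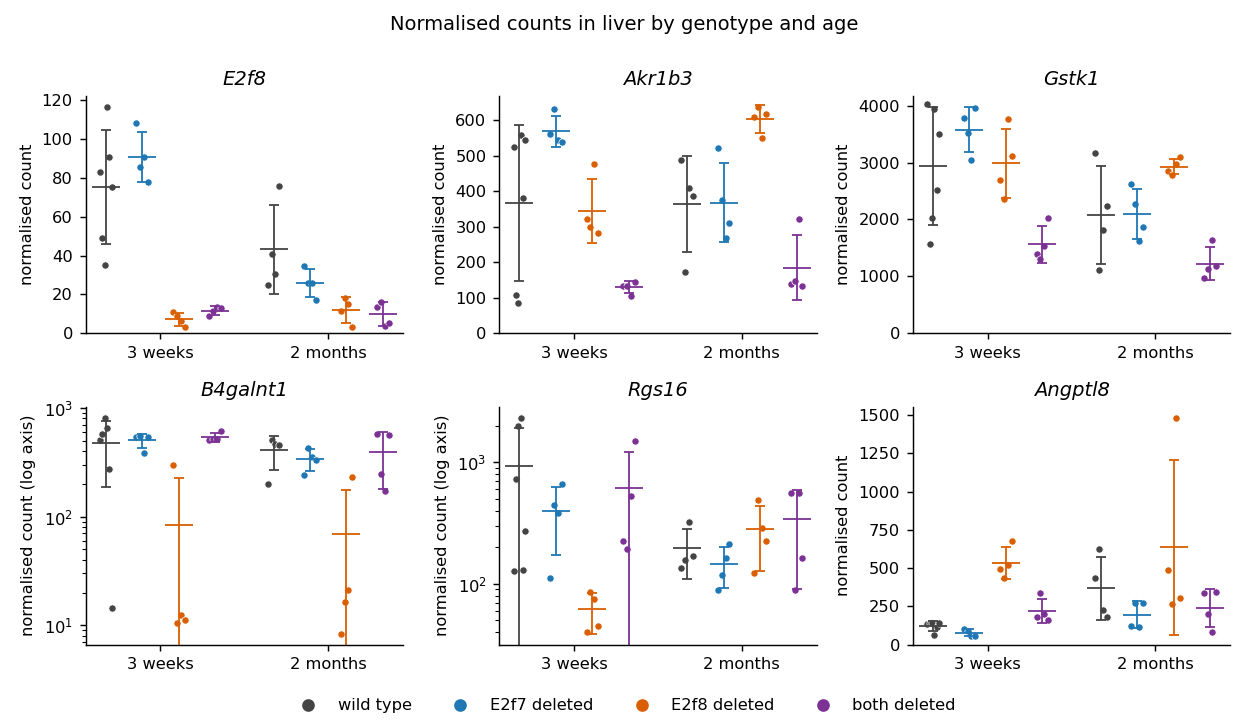
Normalised counts per liver sample (points) with mean and SD (bars) for 6 genes by age and genotype; B4galnt1 and Rgs16 are on a log axis. At 3 weeks the 4 E2f8 mutants had a mean Rgs16 of 61.5 ± 22.6 (SD) against 931 ± 987 in the 6 wild types, and the double mutants had the lowest mean Akr1b3 (129 ± 16.9).

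The double mutants were also set against each single mutant, which asks what the second deletion adds. Against E2f7 mutants at 3 weeks, E2f8 fell (-2.46 log2 or lower), Akr1b3 fell by 2.12 ± 0.39 (from 568 ± 42.4 to 129 ± 16.9), Gstk1 by 1.19 ± 0.25 and the cyclin gene Ccng1 by 0.53 ± 0.14. Angptl8 rose by 1.51 ± 0.43. Those were the 5 calls, with 22 at an unadjusted p under 0.05. Same-numbered samples deviated together here, and with the replicate number as a block 10 genes were called (2 higher, 8 lower). Rises and falls were 2 and 4 under TMM, 2 and 3 with the spike-ins, 0 and 5 with all 10 reference probes and 0 and 6 on the processed signal. Angptl8 lost its call without any of 5 samples (E2f7 mutant replicates 2, 3 and 4, double mutant replicates 1 and 2; adjusted p up to 0.173). Without 4 of these (all but E2f7 mutant replicate 3) Ccng1 lost its call too (up to 0.124) and the count was 3.

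Against E2f8 mutants at 3 weeks, Rgs16 was higher by 3.30 ± 0.76 log2, B4galnt1 by 2.68 ± 0.82 and the protease gene Pcsk6 by 1.18 ± 0.28. Akr1b3 (-1.40 ± 0.38), Ifi203 (-1.12 ± 0.31), Tspyl4 (-0.96 ± 0.22), Gstk1 (-0.93 ± 0.25) and Slc30a10 (-0.88 ± 0.25) were lower. Those were the 8 calls, with 29 at an unadjusted p under 0.05. The count was 2 without double mutant replicate 4, 3 without replicate 2 or 3, 4 without replicate 1 and 5 without E2f8 mutant replicate 3. Rgs16 and Tspyl4 lost their calls only without double mutant replicate 4 (adjusted p 0.0748, with Rgs16 at 2.30, and 0.0558). Without any 1 double mutant, Akr1b3 (up to 0.0748), Ifi203 (0.0991) and B4galnt1 (0.154) lost theirs, as Akr1b3 did without E2f8 mutant replicate 3, Ifi203 without E2f8 mutant replicate 1 or 3 and B4galnt1 without 2, 3 or 4. Gstk1 lost its call without double mutant replicate 1, 2 or 3 or E2f8 mutant replicate 3 (0.0677), and Slc30a10 without double mutant replicate 2, 3 or 4 or E2f8 mutant replicate 1 or 2 (0.125). The B4galnt1 difference was 5.56 without E2f8 mutant replicate 1. List members called as higher were Ccnd1 (1.22, adjusted p 0.0148) without E2f8 mutant replicate 3 and Wee1 (0.74, 0.0287) without E2f8 mutant replicate 4. E2f8 lay at background in nearly all samples of both groups (above it in 1 and 0 of 4).

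At 2 months the double mutants differed from E2f8 mutants in 17 genes (5 higher, 12 lower), with 30 at an unadjusted p under 0.05. B4galnt1 (at least 1.97), Igfbp1 (2.12 ± 0.71), the AP-1 gene Junb (1.67 ± 0.37), Efna1 (1.23 ± 0.33) and Ccne1 (at least 0.066) were higher, with B4galnt1 and Ccne1 above background in 1 of 4 E2f8 mutants each. The retinoic acid hydroxylase gene Cyp26a1 (-2.17 ± 0.47), Myc (-1.93 ± 0.54), Akr1b3 (-1.75 ± 0.38), the succinate receptor gene Sucnr1 (-1.69 ± 0.42) and Angptl8 (-1.37 ± 0.42) were lower most. Akr1b3 was 185 ± 90.8 against 603 ± 38.3 (n = 4 each, adjusted p 0.00198). Under TMM 8 were higher and 9 lower. Without E2f8 mutant replicate 3 the count was 9, and without double mutant replicate 2 or 4 it was 11. Angptl8 lost its call without E2f8 mutant replicate 3 or double mutant replicate 2 or 3 (adjusted p up to 0.742, at -0.52 without E2f8 mutant replicate 3), B4galnt1 without E2f8 mutant replicate 1, 2 or 3 or double mutant replicate 1 or 4 (up to 0.183; 4.70 log2 without E2f8 mutant replicate 4) and Igfbp1 without E2f8 mutant replicate 1, 3 or 4 or double mutant replicate 1, 2 or 3 (up to 0.183). Ccne1 lost its call without E2f8 mutant replicate 3 or double mutant replicate 1 or 2 (0.0683), and Myc without double mutant replicate 4 (0.0745).

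Against E2f7 mutants at 2 months, Junb was the only call of edgeR, at 378 ± 159.6 against 131 ± 50.7 (1.53 ± 0.37 log2, adjusted p 0.0336, 4 of 4 samples). E2f8 lay above background in 1 of 4 E2f7 mutants and 0 of 4 double mutants, and 14 probes had an unadjusted p under 0.05. Under TMM, the spike-ins or all 10 reference probes no probe was called, the processed signal gave 1 higher and 1 lower, and Junb lost its call without E2f7 mutant replicate 1, 2 or 3 or double mutant replicate 1 (adjusted p up to 0.287). Without double mutant replicate 4 the count was 2.

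No list passed fry in these 4 comparisons of mutants, though the E2F family did as lower against E2f7 mutants at 3 weeks with only the groups compared (adjusted p 0.0241; 0.0241 to 0.894 over all alternatives). Against E2f7 mutants, the E2F, G1/S and G2/M lists had adjusted p 0.342, 0.537 and 0.403 at 3 weeks and 0.778, 0.899 and 0.778 at 2 months. Against E2f8 mutants they had 0.812, 0.723 and 0.812 at 3 weeks and 0.99, 0.99 and 0.99 at 2 months. With all samples the list members called were E2f8 against E2f7 mutants at 3 weeks and Ccne1 against E2f8 mutants at 2 months.

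Whether loss of both genes acts differently by age was tested as an interaction in liver. The Id genes, inhibitors of DNA binding, set the ages apart: the double mutant effect was lower at 2 months than at 3 weeks for Id1 (-1.997 ± 0.53 log2, adjusted p 0.028), Id3 (-1.80 ± 0.42, 0.00876) and Id2 (-1.26 ± 0.29, 0.00876). The effects were 0.94, 0.64 and 0.83 at 3 weeks and -1.06, -1.16 and -0.44 at 2 months. No other gene was called by edgeR, and 12 had an unadjusted p under 0.05. E2f8 was not called (adjusted p 0.884) but lay at background in most samples at 2 months, and the E2F, G1/S and G2/M lists had fry adjusted p 0.94, 0.94 and 0.94. All 3 calls were lost without double mutant replicate 2 of 3 weeks (adjusted p up to 0.0769) and on the processed signal. Id1 also lost its call without double mutant replicate 4 of 3 weeks, wild-type replicate 1 or double mutant replicate 2 or 4 of 2 months, or either of 2 unnumbered wild-type samples (up to 0.126).

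Wild-type liver was followed from E13.5 to 2 months to describe how the panel changes with age. Cell cycle genes fell steeply: the cyclin A2 gene Ccna2 fell from 5878 ± 587 normalised counts at E13.5 (n = 3) to 22.2 ± 10.2 at 2 months (n = 4; -6.99 log2 or lower). The ribonucleotide reductase gene Rrm2 (-6.38 ± 0.40), the CDK inhibitor gene Cdkn1c (-5.67 or lower), E2f2 (-4.88 or lower), the replication licensing genes Cdt1 (-4.81 or lower), Mcm6 (-5.35 ± 0.41) and Mcm3 (-5.06 ± 0.28) and the serine synthesis gene Psat1 (-5.14 ± 0.42) fell next. Ccna2, Cdkn1c, E2f2 and Cdt1 were above background in 1 of 4 samples at 2 months. Over the same ages Runx1, a blood cell gene, fell by 1.85 ± 0.31 log2 and Hnf4a, a hepatocyte gene, rose by 2.58 ± 0.18, both picked after their values were seen. The fall of the cell cycle genes was not separated from a change in the share of cell types. Hsd17b6 rose from a level not above background at E13.5 to 2611 ± 1042 (by at least 7.13 log2) and Acox1, the first enzyme of peroxisomal fatty acid oxidation, from 369 ± 8.92 to 11289 ± 2392 (4.93 ± 0.25).

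Other large rises were those of the deubiquitinase gene Usp2 (5.27 ± 0.31), Prlr (at least 3.31), Pcsk6 (4.49 ± 0.37), the kinase gene Plk3 (4.46 ± 0.65, or 3.73 without 2-month replicate 4), Gstk1 (4.25 ± 0.32), Cyp26a1 (at least 3.48), Rgs16 (at least 3.40), the cytokine receptor gene Lifr (3.59 ± 0.24), Sucnr1 (at least 2.49) and Efna1 (3.24 ± 0.39). Of these Prlr, Cyp26a1 and Sucnr1 lay above background in no E13.5 sample and Rgs16 in 1 of 3. In all 49 genes rose and 66 fell of 161. Of the E2F and pocket protein family 8 of 9 members fell, among them E2f4 (-3.34 ± 0.16) and Rb1 (-3.13 ± 0.20), as did all 16 of the G1/S list, among them Mcm7 (-4.57 ± 0.22) and Pcna (-4.48 ± 0.23). All 9 of the G2/M list fell, among them Fzr1 (-3.35 ± 0.16) and Pttg1 (-4.26 ± 0.27). Adjusted over the list alone the counts were the same. Fry gave adjusted p 4.95e-23, 3.41e-21 and 1.46e-21, and the lists' median changes were -3.13, -4.30 and -3.35. E2f8 fell from 645 ± 61.1 to 43.2 ± 22.9 and E2f7 from 148 ± 13.6 to 16.4 ± 5.02, each above background in 1 of 4 samples at 2 months.

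The 2 ages lay in different lane sets. Within set 1 the wild types at 2 months also differed from those at 3 weeks. Their backgrounds were 34.4 to 58.1 counts against 19.6 to 31.0. Their ratio of the 2 highest spike-ins was 0.388 to 0.4136 against 0.3355 to 0.3563. A block by lane set leaves this difference within set 1 in place. With the lane set as a block, made possible by the 3-week wild types that lay in all 3 sets, 43 genes rose and 62 fell, and Rgs16 alone of the genes named lost its call (1.09 log2, adjusted p 0.386, the highest of its alternatives, where the lowest was 6.19e-07). Rises and falls were 77 and 44 with all 10 reference probes and 39 and 81 with the spike-ins, with the median probe at 0.51 and -0.74 against -0.21. A test over all 8 wild-type groups, the weaned livers included, called 142 of 161 probes. The 10 with the smallest p were E2f4, Fzr1, Cdkn1c, Mcm7, E2f2, Ccne1, Pcna, Ccna2, Mcm3 and Orc2, each highest at E13.5. Cdkn1c was 550.0 ± 71.1 at birth, 1205 ± 475 at 1 week and 83.1 ± 16.1 at 2 weeks (n = 2 each).

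**Figure D3:**
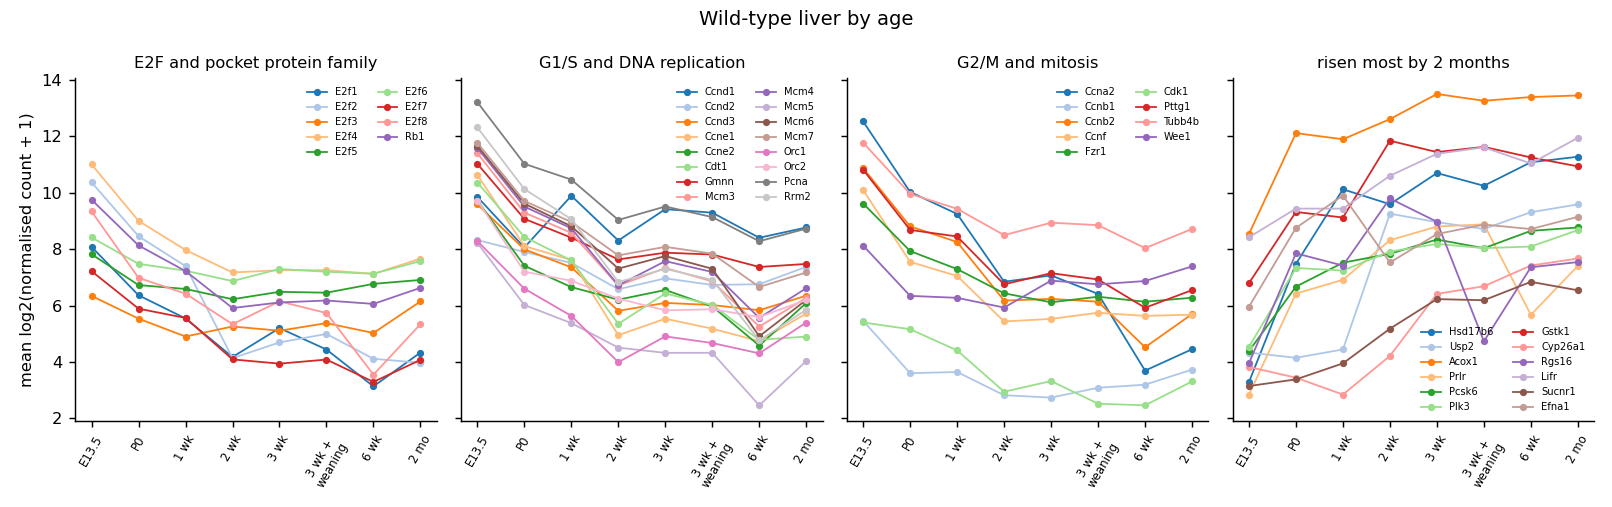
Mean log2 of the normalised count plus 1 (vertical axis) in 8 wild-type liver groups by age, the weaned livers shown apart, for the members of 3 fixed lists and the 12 genes that rose most by 2 months. All 16 G1/S members and all 9 G2/M members were lower at 2 months than at E13.5, and n is 2 to 6 per age.

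Livers taken 1 day after weaning were compared with other 3-week livers. Ugt2b37, a glucuronosyltransferase gene, rose from 118 ± 63.7 (n = 6) to 571 ± 133 (n = 3; 2.27 ± 0.47 log2, adjusted p 0.000962). Myc (1.60 ± 0.49), the stress response gene Gadd45a (1.501 ± 0.31), Id3 (1.27 ± 0.30) and Id2 (1.04 ± 0.21) rose too. Rgs16 fell from 931 ± 987 to 27.2 ± 11.9 (-5.09 ± 0.93), and Igfbp1 (-3.46 ± 0.80, or -1.96 without replicate 4 of the other livers) and the hedgehog receptor gene Ptch1 (-0.55 ± 0.17) fell. Those were the 8 calls, each in 3 of 3 samples, with 29 at an unadjusted p under 0.05. No list passed fry (adjusted p 0.605 for the E2F family, 0.246 for G1/S and 0.605 for G2/M) and no member was called, though adjusted over the list alone E2f1 passed (-0.83 ± 0.28). The weaned samples lay in lane set 3 with only 2 of the 6 others: within that set 2 genes were called, Id2 (1.18 log2) and Rgs16 (-2.88), and Igfbp1 was at -0.80. Within it the G1/S list passed fry as lower (adjusted p 0.00729; 0.00488 to 0.884 over all alternatives), and rises and falls over all samples were 10 and 2 with the spike-ins and 44 and 2 on the processed signal. Without weaned replicate 2 the count was 5, as Myc, Ptch1 and Id3 (adjusted p 0.0524) lost their calls. Myc also lost its call without weaned replicate 1, replicate 3 or 4 of the other livers or 3 of the unnumbered ones (up to 0.325), and Ptch1 without weaned replicate 1 or 3, replicate 3 or 4 of the others or 2 unnumbered ones (up to 0.325). E2f1 was called without replicate 3 of the others (0.00724).

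Giant cells at E10.5 were compared across genotypes to ask which genes depend on E2f7 and E2f8 there. On the raw counts scaled by reference probes Tpbpb, a trophoblast specific gene, was higher in all 3 mutant genotypes. The processed signal gave the other direction and TMM scaling no call, as described below. Tpbpb was 376 ± 181 normalised counts without E2f7, 199.9 ± 69.2 without E2f8 and 328 ± 89.5 without both (SD, n = 2 each). Wild type had 10.1 ± 10.9, with 1 of 2 samples above background. The log2 changes were 5.20 ± 1.35 (adjusted p 0.00341), 4.30 ± 1.29 (0.0171) and 5.01 ± 1.34 (0.0106). Without E2f7, the spongiotrophoblast marker Tpbpa (4.24 ± 0.99) and Creg1 (3.32 ± 1.13) were higher too and the connexin gene Gja1 lower (-1.18 or lower). Without E2f8, Prl3d1, which encodes placental lactogen I, fell from 1859 ± 1378 to 66.1 ± 11.7 (-4.81 ± 1.21, adjusted p 0.00439), and Gja1 (-0.97 or lower) and Rrm2 (-3.05 ± 0.96) were lower. No mutant of these 2 groups had Gja1 above background.

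Of 53 probes edgeR called 3 higher and 1 lower without E2f7, 1 and 3 without E2f8, and 1 and 0 without both, with 9, 15 and 9 at an unadjusted p under 0.05. Against E2f7 mutants, the double mutants had less Tpbpa (-4.77 log2 or lower, above background in neither double mutant), the single call (1 at an unadjusted p under 0.05). Against E2f8 mutants they had more Prl3d1 (1776 ± 258, 4.74 ± 1.21), also the single call (2). Of the giant cell genes Hand1, Prl2c2 and Prl3d1, 0, 1 and 0 were called in the 3 mutants against wild type (fry adjusted p 0.57, 0.34 and 0.988). Of 8 G1/S members 0, 1 and 0 were called (0.446, 0.34 and 0.22) and of 3 G2/M members 0 (0.446, 0.34 and 0.569). Between mutants, the giant cell, G1/S and G2/M lists had adjusted p 0.855, 0.855 and 0.866 against E2f7 mutants and 0.389, 0.593 and 0.9 against E2f8 mutants. In those 2 comparisons the 1 list member called was Prl3d1. Adjusted over the list alone the counts were the same in all 5 comparisons.

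The direction against wild type depends on the table and the scale. The reference probes B2m, Gapdh and Oaz1 lay above background in both wild types but in replicate 2 of no mutant genotype. In the raw counts the median probe of the mutants was 1.08, 0.97 and 1.16 log2 above wild type and the negative controls were 1.14, 1.53 and 1.62 above it, so a probe at background also appears raised. Under TMM, which sets the median near 0, Tpbpb was 4.11, 3.51 and 3.82 log2 higher, past the threshold in no mutant. Under TMM the E2f7 and double mutants had no call and the E2f8 mutants 0 higher and 3 lower, with the spike-ins 0, 0 and 5 lower, and with all 10 reference probes 3 higher and 2 lower, 1 and 3, and 1 and 0. On the processed signal, whose wild-type E10.5 columns do not follow the raw counts, 42, 43 and 42 probes were lower and 0, 0 and 1 higher, and Tpbpb was lower in all 3 (-6.88, -7.69 and -7.07 log2). With n = 2, single samples decide most calls: without wild-type replicate 1 Tpbpb lost its call in all 3 mutants (4.39, 3.48 and 4.20 log2, adjusted p 0.168, 0.376 and 0.323). Without E2f8 mutant replicate 1 or 2 none of the 4 calls of E2f8 mutants against wild type, nor the Prl3d1 call of the double mutants, remained (adjusted p up to 0.202 and 0.672). Without wild-type replicate 2 the E2f8 mutants lost Gja1 and Rrm2 (adjusted p 0.52597 each), which left 2, and Rrm2 was at -1.48 log2.

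For the E2f7 mutants the count was 2 without wild-type replicate 1 or 2 or mutant replicate 2, and without wild-type replicate 1 only Gja1 of the 4 calls remained. Creg1 was lost without any of these 3 (adjusted p up to 0.378, at 2.69 log2 without mutant replicate 2), Tpbpa without wild-type replicate 1 (3.33, 0.0681) and Gja1 without wild-type replicate 2 or either mutant (0.553). Rrm2 was called lower without wild-type replicate 1 (-3.25, 0.0262), and Prl3d1 without E2f7 mutant replicate 1 (-5.27 against -1.09 with it, 0.025), a sample without which Prl3d1 was also called between double and E2f7 mutants (5.20, 0.0415, 2 calls). Tpbpb in double mutants lost its call without double mutant replicate 2 too (0.0955). Without wild-type replicate 2 the rise of Tpbpb was 7.21, 6.30 and 7.02 log2 in the 3 mutants and that of Tpbpa 7.33 in E2f7 mutants, and without E2f7 mutant replicate 2 that of Tpbpb was 4.60. In E2f8 mutants the change of Prl3d1 was -3.74 without wild-type replicate 1 and -5.42 without replicate 2, and that of Rrm2 was -3.78 without replicate 1.

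**Figure D4:**
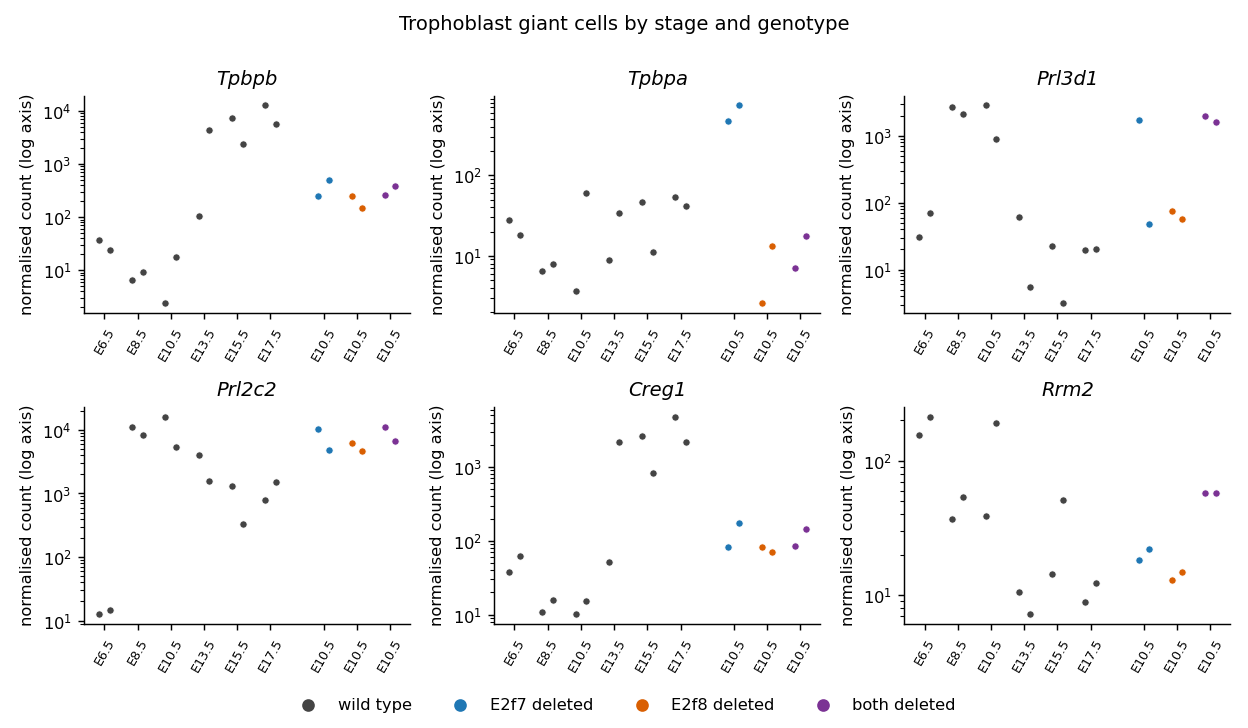
Normalised counts per giant cell sample (points, log axis) for 6 genes, by stage in wild type (left) and at E10.5 in the 3 mutant genotypes (right), n = 2 each. At E10.5 the 2 wild-type samples have a mean Tpbpb of 10.1 ± 10.9 (SD) against 328 ± 89.5 in double mutants, a difference that turns round on the processed signal, and by E17.5 wild type reaches 9200.2 ± 4844.

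Whether loss of both genes acts differently in giant cells at E10.5 and in liver at 3 weeks was tested in a joint fit, in which tissue and kind of deletion go together. The effect was higher in giant cells for Creg1 (3.32 ± 0.77 log2) and lower for Rrm2 (-1.84 ± 0.62). Tpbpb, Gprc5a, Rab27a, E2f8 and Ccnd3 were called higher too, but each lay near background in at least 1 of the 4 groups, so no size is given. Rab27a was above background in no giant cell sample of either group and E2f8 in 1 of 4, and Tpbpb was so in 1 of 10 liver samples, so their calls compare an effect in 1 tissue with counts near background in the other. In all 16 were higher and 1 lower of 164, with 44 at an unadjusted p under 0.05. E2F family members called higher were E2f4 (1.62 ± 0.54) and, near background, E2f8, 2 of 9, and fry called the family higher (adjusted p 0.0337), though not without E2f7 and E2f8 (0.0793; 1.48e-09, reversed, to 0.362 over all alternatives). E2f7, near background in both tissues, was not called. G1/S members called were 5 higher, among them Ccnd3, Gmnn (1.95 ± 0.55) and Mcm7 (1.81 ± 0.57), and 1 lower of 16 (fry adjusted p 0.0337), and adjusted over the list alone 8 were higher and 1 lower. The G2/M (0 of 9), other trophoblast (0 of 3) and giant cell (0 of 3) lists had adjusted p 0.107, 0.801 and 0.801.

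Most of this excess is the shift of all probes, 1.05 log2 at the median: under TMM 1 gene was higher and 2 lower, with the spike-ins 1 and 12, and on the processed signal 2 and 126. With the spike-ins the 2 lists turned round and passed no threshold (adjusted p 0.131), and without double mutant giant cell replicate 2 or wild-type replicate 2 the count was 1 or 3, and without double mutant replicate 1 it was 28. Without double mutant giant cell replicate 2 every gene named but Tpbpb lost its call (adjusted p up to 0.5; E2f4 was at 0.93 log2), as did both lists (0.388), which also ended without wild-type giant cell replicate 1 or 2. Gprc5a, E2f4, Gmnn and Mcm7 lost theirs without either wild-type giant cell sample, Ccnd3 without replicate 1, and E2f8 (0.0896), Rab27a (0.161) and Rrm2 (0.861) without replicate 2. Rrm2 also depended on double mutant giant cell replicate 1, double mutant liver replicates 3 and 4, wild-type liver replicate 3 and 2 unnumbered ones, E2f4 on double mutant liver replicates 1, 2 and 3 and 3 unnumbered wild types, and Mcm7 on double mutant liver replicate 1. Rrm2 was at -2.57 log2 without wild-type giant cell replicate 1 and at -0.26 without replicate 2. Ccna2 was called higher without double mutant liver replicate 4 (0.0342) and Fzr1 without double mutant giant cell replicate 1 (0.045), both near background in giant cells.

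In wild-type giant cells E17.5 was set against E6.5 to describe the course of the panel. The reference probes Gapdh and Oaz1 were above background in no sample of either stage, and B2m only in E17.5 replicate 1. These probes thus bring mostly background counts into the scale of this comparison. Tpbpb rose from 30.8 ± 10.1 to 9200.2 ± 4844 (n = 2 each; at least 7.70 log2, adjusted p 8.58e-06), Creg1 from 49.9 ± 16.9 to 3491 ± 1863 (6.12 ± 1.29) and the proliferin gene Prl2c2 from a level not above background to 1135 ± 499.6 (at least 4.68). Tsc22d1 rose as well (at least 2.03), while Rrm2 (-2.58 or lower) and Gja1 (-1.74 or lower) fell. Tpbpb, Prl2c2 and Tsc22d1 lay above background in no E6.5 sample, Creg1 in 1 of 2, and Rrm2 and Gja1 in no E17.5 sample. Between these ends Prl2c2 was 9769 ± 2151 at E8.5 and 10762 ± 7596 at E10.5, and Prl3d1 was 50.7 ± 28.7 at E6.5, 2394 ± 414 at E8.5 and 33.7 ± 40.0 at E13.5. The 4 rises and 2 falls were the calls of edgeR among 53 probes (10 at an unadjusted p under 0.05). Of the giant cell genes 1 of 3 rose (fry adjusted p 0.215), of the G1/S list 1 of 8 fell (0.237) and of the G2/M list 0 of 3 was called (0.789), with the same counts adjusted over the list alone. The giant cell list passed as higher under TMM (0.0304), with probes of a group mean of at least 50 (0.0487) and with background subtracted (0.0191). The G1/S list passed as lower with only the groups compared (0.00447). On the processed signal all 3 lists passed as higher. Over all alternatives the giant cell, G1/S and G2/M lists spanned 4.05e-07 to 0.858, 4.03e-05 to 0.952 and 5.61e-06 to 0.952. A test over all 6 stages called 10 probes: Tpbpb, Prl3d1, Creg1, Prl2c2, Rrm2, Gja1, Cdkn1c, Tsc22d1, Lifr and the histone gene H2bc1.

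The early and late stages lay in different lane sets, so set and stage cannot be told apart here. On the processed signal 41 probes rose and 2 fell from E6.5 to E17.5, with Rrm2 (2.36) and Gja1 (3.09) turned round, and Rrm2, Gja1 and Tsc22d1 lost their calls without E17.5 replicate 1, which left 3 (adjusted p 0.0823, 0.0958 and 0.0823). Creg1 was at 5.44 log2 without that sample. Gja1 also lost its call without E17.5 replicate 2 (0.16), Prl2c2 without either E6.5 sample (up to 0.0705) and Tsc22d1 without E6.5 replicate 2 (0.135). The test over all stages called 74 probes without E15.5 replicate 1 and 38 without E15.5 replicate 2. In it Tsc22d1 lost its call without E6.5 replicate 2 or E17.5 replicate 1 (up to 0.118), Lifr without either E8.5 sample (0.0794) and H2bc1 without any sample of E6.5, E8.5 or E10.5 (0.365).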

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

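The 13 counts of genes called under other splits of the samples were planned; leaving the deleted genes out of them, keeping pairs apart in 1 of them, the 12 counts within lane sets, and the tests of lane sets, shallow lanes, strain variants, exchanged columns and scaling were chosen only after the results were seen.

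Single samples lay far from the others of their group, beyond the gap that Dixon's test allows, in 14 of 138 groups of values. That gap is passed by about 1 in 20 groups of independent, normally distributed values. These counts were not put on a log scale, came mostly from genes named for their calls and shared samples. No excess over chance is thus shown. In wild-type liver at 3 weeks, replicate 4 had an Igfbp1 of 14560.3 (next 2839.5), an Angptl8 of 59.3 (next 113) and a Ptch1 of 305 (next 193), and replicate 3 had a Tspyl4 of 19.7 and a Map2k6 of 187. In E2f7 mutants at 3 weeks replicate 2 had an E2f7 of 24.9. In E2f8 mutants at 3 weeks replicate 3 had a Ptgds of 50.6, replicate 1 a B4galnt1 of 299 (next 12.5) and replicate 4 a total count of 52635. In double mutants B4galnt1 was 618 in replicate 4 at 3 weeks and Akr1b3 was 321 in replicate 3 at 2 months. At 2 months B4galnt1 was 231 in E2f8 mutant replicate 4, Ccna2 was 37.6 in wild-type replicate 1 and Plk3 was 1095 in wild-type replicate 4.

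The effect of losing both genes differed, by a test of the interaction, between 2 months and 3 weeks in liver for Id1 (-1.997 log2), Id3 (-1.80) and Id2 (-1.26). It differed between giant cells and liver for Creg1 (3.32) and Rrm2 (-1.84). Tpbpb (adjusted p 0.000379), Gprc5a (0.0241), Rab27a (0.025) and E2f8 (0.025) passed this test too, but with groups near background, so no size is given. Other values came from data that the comparisons within liver or within giant cells did not use. The trophoblast genes Tpbpa and Tpbpb, below the limit for testing in liver though part of the joint fit with giant cells, had 206 and 75 raw counts in 1 unnumbered wild-type liver sample at 3 weeks, where the next highest liver samples had 31 and 41 and its background was 17.8. Without that sample Tpbpb still passed the test between tissues (adjusted p 0.00107). The 10 processed columns of wild-type giant cells from E8.5 on did not follow from the raw counts. With the 21 probes of unsettled label put in an inferred order, 17 of 19 tested were called over the wild-type liver groups and 13 between 2 months and E13.5 (2 higher, 11 lower).

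The first pattern weighed is the fall of Akr1b3 and Gstk1 in double mutant liver at 3 weeks. A difference between lane sets is argued against by the size of the falls, as the smallest of the 4 within lane sets 1 and 2 was -0.85 log2. Lane set 2 held 1 double mutant and 1 wild type, so 2 of these 4 compare single samples. With wild types of lane sets 1 and 2 alone only 1 gene of this comparison was called, so at least 1 of the 2 calls was lost. The size of the fall argues against shallow samples, as the smaller fall without the 4 shallow ones was -0.90 log2 (adjusted p 0.0484). The calls are less firm. Double mutant replicate 3 was the only shallow sample in this comparison, and without it alone both genes lost their calls. The 2 genes lie on the same chromosome, and over 40 liver samples of other groups they deviated together from their group means (r = 0.835, permutation p 2e-05 of 100000 resamples; Spearman's rho 0.733, p 8e-05), above 99.96 percent of 12880 pairs of probes. A strain variant that both genes share would give such a correlation. The correlation cannot tell it from another source that moves both genes together, so this variant stays open. Loss of both E2F genes stays open too, untested against it.

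The second pattern is B4galnt1, near background in 3 of 4 E2f8 mutants at each age. Loss of E2f8 as the whole cause is argued against, since double mutants, which lack E2f8 too, were higher than E2f8 mutants, the smaller fitted difference of the 2 ages being 2.58 log2 (adjusted p up to 0.0447), a call that single samples can end. Samples under 30 normalised counts, a limit set after the values were seen, were 6 of 8 E2f8 mutants, 1 of 10 wild types (14.4 at 3 weeks), 0 of 8 E2f7 mutants and 0 of 8 double mutants. B4galnt1 and E2f7 lie on the same chromosome, but a strain variant near E2f7 stays open: the pattern was seen in samples lacking E2f8, so those with E2f8 intact would have to test it, and there 0 of 8 against 1 of 10 decide nothing (Fisher's exact p 1). A loss of E2f8 that acts only with E2f7 intact stays open too, untested.

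The third pattern is the mismatch of raw and processed wild-type giant cell values. The authors' scaling alone is argued against, since r across probes fell to 0.481 where a scale keeps it near 1. An exchange of columns between samples in 1 of the tables is argued against too, since the highest r of any of the 10 processed columns with the raw column of any sample was 0.8438, where the other 52 columns reached at least 0.979. By stage means, processed E10.5 had r 0.738 with raw E15.5 against 0.455 with raw E10.5. Processed E13.5 had 0.763 with raw E10.5 against 0.438 with its own, while processed E15.5 was closest to its own (0.794). Values from samples outside the raw table, and stage labels exchanged among such samples, stay open, untested. No biological explanation was tested, as both tables carry the same sample labels.

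Other splits of the same samples were set against the number of genes called, with E2f7 and E2f8 not counted in the comparisons of mutants. Without regard to lane set, a share of splits under 0.05, the real split included, reached the real count in these comparisons. For E2f8 mutants at 3 weeks it was 2 of 100 (23 genes, highest other 27). For 2 months against E13.5 it was 1 of 35 (115, highest 102). Double against E2f8 mutants had 1 of 35 at 3 weeks (8, highest 4) and 1 of 35 at 2 months (17, highest 1). After weaning it was 2 of 84 (8, highest 13). In the comparisons of E2f8 mutants with wild type, of ages and after weaning, the groups held unequal lane sets. There these splits cannot tell the groups from the lane sets, so chance is not excluded. For double against E2f7 mutants at 3 weeks, same-numbered samples deviated together and were kept apart. Only 8 splits part all 4 pairs, too few for a share under 0.05 (real 4, highest other 0). The other 27 splits, which keep some pairs on 1 side, gave at most 1.

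For E2f7 mutants the real count was 0 at both ages, which every split must reach, so the splits decide nothing there. They were 100 of 100 at 3 weeks (highest 10) and 35 of 35 at 2 months (highest 1). Chance is not excluded for E2f8 mutants at 2 months (3 genes, 2 of 35 splits, highest 4). It is not excluded either for double mutants at 3 weeks (4, 10 of 100, highest 13) and 2 months (2, 2 of 35, highest 2). Nor is it for the effect at 2 months against 3 weeks (3; 7 of 100, highest 7) and double against E2f7 mutants at 2 months (1; 3 of 35, highest 24). In the last, the split with 24 put both samples of lane set 2 on 1 side, which points to a structure by lane set; with lane set as a block the real count was 1. The highest splits for the E2f7 and double mutants at 3 weeks and the E2f7 mutants at 2 months also put both samples of lane set 2 on 1 side, and their blocked counts were 3, 11 and 3. The highest splits for E2f8 mutants at 3 weeks and after weaning parted samples of lane set 3 from most others, and their blocked counts were 33 and 2, E2f8 included.

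These splits ignore the lane sets. With lane set as a block and samples exchanged only within lane sets, chance is not excluded for the effect at 2 months against 3 weeks (4; 9 of 100 splits, highest 8). For the other comparisons of mutants there are 20 such splits (8 where pairs are kept apart) and after weaning 10, too few for a share under 0.05. The real count and the highest other were 3 and 3 for E2f7, 32 and 9 for E2f8 and 10 and 9 for double mutants at 3 weeks, and 3 and 1, 8 and 6, and 2 and 3 at 2 months. For double against E2f7 and E2f8 mutants they were 9 and 0, and 14 and 6 at 3 weeks, and 1 and 0, and 19 and 1 at 2 months, and after weaning 2 and 1. For 2 months against E13.5 no lane set holds both ages.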

How the results depend on the processing

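The scales from all 10 or all 6 listed reference probes, background subtraction, the unsettled probes included, the fits without 4 shallow samples, within lane set 3 or without 1 liver sample with trophoblast counts, the lists without E2f7 and E2f8, and the crossed pairing were chosen only after the results were seen.

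Of the 94 calls of named genes in liver, 50 kept their direction and their side of the threshold under every alternative run, 59 in every fit without 1 sample, and 48 in both. In giant cells the numbers were 27, 10, 10 and 7, and for the difference between tissues 10, 0, 1 and 0. Over all 131 such calls, DESeq2 with reference probe size factors kept 130, TMM scaling 111, the spike-in scale 104 (3 reversed), and the processed signal plus 1 kept 99 and plus 10 kept 98 (19 reversed in each). No call reversed under the other alternatives or without 1 sample. Changes in the counts of calls follow by alternative, and their cause was not tested unless stated.

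With another scale, E2f7 mutants at 3 weeks had 1 call and at 2 months 1 (TMM, spike-ins, all 10 or all 6 listed probes), and double against E2f7 mutants at 2 months had 0. E2f8 mutants at 2 months had 2 with all 6 listed probes. Double mutants at 3 weeks had 11 with the spike-ins. In giant cells, TMM and the spike-ins gave 0 for the E2f7 mutants, the double mutants, and double against E2f8 mutants. The test over all stages gave 19 under TMM, 17 with the spike-ins and 16 with all 10 probes, and the difference between tissues gave 3 under TMM. With the spike-ins E2f4 (-0.40), Gmnn (-0.0316) and Mcm7 (-0.0908) reversed in the difference between tissues, as did the E2F and G1/S lists (adjusted p 0.131 each). Leaving out 1 reference probe gave as few as 2 calls in E2f8 mutants at 2 months, 0 in double against E2f7 mutants at 2 months and 2 in E2f8 mutant giant cells, and as many as 17 over all giant cell stages.

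DESeq2 with its own size factors gave 2 calls in E2f7 mutants at 3 weeks and 1 at 2 months, 8 in double mutants at 3 weeks, 7 in E2f8 mutants at 2 months, 8 in double against E2f7 mutants at 3 weeks, 0 in double mutant giant cells, 4 between tissues and 17 over all giant cell stages. With reference size factors it gave 2, 1, 8, 9 (double against E2f7 mutants at 3 weeks) and 16 (all stages).

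Background subtraction gave 1 call in E2f7 mutants at 3 weeks, 0 in double against E2f7 mutants at 2 months, 0 in each of the 3 mutant giant cells and in double against E2f8 mutant giant cells, and 11 between E17.5 and E6.5. Without a dispersion trend double mutant giant cells had 2 calls. Without the probe filter, which adds probes to the adjustment, E2f8 mutant giant cells had 1.

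Fitting only the groups compared gave 9 calls in E2f8 mutants at 3 weeks, 0 in double mutants and in double against E2f7 mutants at 2 months, 16 in E2f7 and 3 in double mutant giant cells, and 17 between E17.5 and E6.5. This uses fewer samples for the spread. Lane set 1 alone gave 7 in E2f7 mutants at 3 weeks and 1 at 2 months, 7 in E2f8 and 0 in double mutants at 2 months, and 12 and 2 in double against E2f7 mutants at 3 weeks and 2 months. Wild types of lane sets 1 and 2 alone at 3 weeks gave 1 in double mutants and 13 after weaning. Without 4 shallow samples there was 1 call in E2f7 mutants at 2 months, 3 in double against E2f8 mutants at 3 weeks and 0 in double against E2f7 mutants at 2 months. Without the liver sample with trophoblast counts E2f7 mutants at 3 weeks had 1.

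With lane set as a block E2f7 mutants had 3 calls at each age, double mutants at 3 weeks 11, E2f8 mutants at 2 months 9, double against E2f7 and E2f8 mutants at 3 weeks 10 and 14, and the weaned livers 2, as within lane set 3 (2). For giant cells this block could not be fitted.

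With the replicate number as a block, E2f7 mutants had 2 calls at 3 weeks and 1 at 2 months, double mutants at 3 weeks 3, E2f8 mutants at 2 months 7, double against E2f7 and E2f8 mutants at 3 weeks 10 and 13, and weaned livers 15. The other counts of calls stayed within 1.5 times under this block. Among comparisons with at least 3 shared numbers, only in double against E2f7 mutants at 3 weeks did all pairs deviate together. There 3 of 4 samples correlated best with their own number. Giant cells at E10.5, with 2 pairs each that give the same r, also deviated together in most comparisons. For E2f7 and E2f8 mutants against wild type r was 0.351 and 0.165, and for double mutants 0.0526. For double against E2f7 and E2f8 mutants it was 0.424 and 0.434. Replicate 1 had the higher total count in each of these groups, so depth cannot be told apart from a pairing there. Same-numbered giant cells of E6.5 and E17.5 deviated apart (r = -0.168), and with the numbers crossed as a block the count was 6.

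On the processed signal plus 1 and plus 10, E2f7 mutants at 2 months had 1 and 1 calls, double against E2f7 mutants at 2 months 2 and 0, and the difference between ages 0 and 0. E2f7, E2f8 and double mutant giant cells had 42 and 42, 43 and 42, and 43 and 43. Double against E2f7 and E2f8 mutant giant cells had 0 and 0, and 2 and 2. The difference between tissues had 128 and 117, weaned livers 46 and 50, all stages 45 and 48, and E17.5 against E6.5 43 and 44. The wild-type giant cell columns of this table do not follow from the raw counts.

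Reversed values on the processed signal plus 1 and plus 10 were these in log2. In E2f7 mutant giant cells they were Tpbpb -6.88 and -6.85, Tpbpa -4.41 and -4.40, and Creg1 -7.58 and -7.49. Tpbpb was -7.69 and -7.64 in E2f8 and -7.07 and -7.04 in double mutants. Between tissues they were E2f8 -1.22 and -0.97, Tpbpb -5.33 and -6.14, Creg1 -7.39 and -7.30, Gprc5a -0.26 and -0.40, Rab27a -2.90 and -1.89, E2f4 -1.90 and -1.68, Ccnd3 -0.78 and -0.60, Gmnn -2.06 and -1.87, and Mcm7 -1.69 and -1.49. Over stages Rrm2 was 6.76 and 6.70 and Gja1 6.82 and 6.73, and at E17.5 against E6.5 Rrm2 was 2.36 and 2.32 and Gja1 3.09 and 3.00. Ptch1 in weaned livers was 0.0196 and 0.0173. Between tissues E2f8, Tpbpb, Gprc5a, Rab27a and Ccnd3 rest on groups near background. The E2F and G1/S lists between tissues were lower with adjusted p 1.48e-09 and 1.63e-09, and 2.56e-07 and 1.28e-06.

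Of the gene lists, 6 passed fry. Without E2f7 and E2f8 the E2F family lost its call in E2f7 mutants at 2 months (adjusted p 0.0807) and between tissues (0.0793), and no other list changed sides. Lists that passed only under an alternative were the E2F family as lower in E2f8 mutants at 2 months under TMM (0.0442; 0.0442 to 0.973 over all alternatives) and in E2f8 and double mutants at 3 weeks on the processed signal (0.0255 and 0.0111; up to 0.978 and 0.969), and as higher after weaning on the processed signal (0.0126; up to 0.948). In double mutant giant cells the G1/S list passed as higher with background subtracted (0.0451) and as lower on the processed signal (1.18e-05; up to 0.577). On that signal the giant cell, G1/S and G2/M lists passed as lower in all 3 mutants. With the spike-ins the G2/M and other trophoblast lists passed as lower between tissues (0.0248 and 0.00622; up to 0.796 and 0.979), as they did on the processed signal (1.48e-09 and 1.93e-14 with 1 added, 4.62e-09 and 1.50e-17 with 10). The giant cell list passed as lower there with 10 added (0.0477; up to 0.992). The E17.5 lists, the double against E2f7 mutant lists and the G1/S list after weaning are given above. The number of lists passing was 3 with all 6 listed reference probes, 3 with the unsettled probes included, 3 without each list's most changed gene, and 22 and 23 on the processed signal plus 1 and plus 10.

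Leaving out each sample in turn, the lowest and highest counts were 0 and 4 in E2f7 mutants at 3 weeks, 16 and 26 in E2f8 mutants and 1 and 5 in double mutants. At 2 months they were 0 and 1, 1 and 5, and 0 and 4. Double against E2f7 mutants gave 3 and 6 at 3 weeks and 0 and 2 at 2 months, and double against E2f8 mutants 2 and 8, and 9 and 21. The difference between ages gave 0 and 4, 2 months against E13.5 109 and 115, all wild-type liver groups 138 and 146, and weaned livers 5 and 10. In giant cells E2f7, E2f8 and double mutants gave 2 and 4, 0 and 4, and 0 and 1. Double against E2f7 and E2f8 mutants gave 1 and 2, and 0 and 1, E17.5 against E6.5 3 and 5, and all stages 8 and 74. The difference between tissues gave 1 and 28. Where this leaves 1 giant cell sample in a group, that sample is assumed to vary like the other groups.

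Signal over background limits what could be tested: 18 of 179 probes in liver and 126 of 179 in giant cells were not above it in every sample of any group.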

Other observations

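The test of whether E2f8 mutant changes recur at 2 months was chosen only after the result was seen.

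The hypothesis was that the genes called in E2f8 mutant liver at 3 weeks change the same way at 2 months. Of the 23 called genes other than E2f8, 18 went the same way at 2 months, but 7 of the 70 splits of those 8 samples, each direction counted, reached that number and the highest other split gave 19. The number at 2 months is thus not beyond chance.

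In lists with fewer than 3 tested probes, which were not tested as lists, single genes of wild-type liver changed from E13.5 to 2 months. They were chosen after their values were seen: the hepatocyte factor gene Hnf4a rose by 2.58 ± 0.18 log2 (adjusted p 4.74e-16) and the blood cell gene Runx1 fell by 1.85 ± 0.31 (adjusted p 1.65e-06), each in 4 of 4 samples.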
